A study of Mus musculus with 30 samples.

How the data were processed

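Tissue of 30 tibialis anterior samples from male mice was homogenised in Trizol, and libraries made with a TruSeq stranded mRNA kit were sequenced on a NovaSeq instrument, per the labels, which call the samples biological replicates. The deposited table holds TPM made by the authors, with 1 column for each of the 30 samples and 1 line per gene symbol, and every column sums to 1000000. The genome build was mm10, per the processing notes. The aligner, the counting tool, its strand setting, the gene annotation and any filter are not given in the sources used here. Within a gene, the low values of different libraries stand in ratios of whole numbers after 1 factor per library, so whole reads were counted and divided by a gene length that is the same in every library.

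Whole reads were recovered from these steps for all 23193 genes above 0 (tolerance of 0.05 read), for 16163 with the summed exon length of the annotation and for 7030 with the shortest other length that made all values whole, so the reads of the latter may be low by a whole factor. Recovered totals ranged from 27.4e6 to 55.0e6 per library. A floor of 3 reads corresponds to 0.0837 TPM for a gene 2 kb long in the library old 2. Reads were not marked by molecular identifiers, so read numbers speak for counting error alone. Gene coordinates came from GENCODE M21 (mm10), to which 45084 symbols matched directly, 609 by an older symbol and 1950 not at all. No column was left unused.

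Samples were grouped by their labels into 8 groups of 4 experiments, and each experiment was compared within itself. Values were log2(TPM + 1), with a pseudocount of 1, for genes with a TPM of at least 1 in at least as many libraries as the smaller group holds. limma 3.58.1 in R 4.3.3 fitted each pair of groups with a variance trend, and genes were called at a Benjamini-Hochberg adjusted p under 0.05, two-sided. The response to LLC, dexamethasone and old age was compared in a fit of 22 libraries with interaction terms. Shared calls were tested by Fisher's exact test (two-sided) against all genes tested in both comparisons, adjusted over 24 tests. Cyr61 was also tested by an exact permutation test on log2 values (two-sided).

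A set of 35 gene lists (pathways and cell type markers) was written down and tested by camera at a preset correlation of 0.01, again with an estimated correlation, and by fry, with p adjusted over the lists. camera asks whether a list ranks apart from the other genes, and fry whether its genes move on balance in 1 direction. Counts of members are given over all genes tested and adjusted over the list alone. The groups, comparisons, lists, thresholds, alternatives and the rule for naming genes were chosen before the data were examined. That rule took up to 10 increases and 10 decreases, the largest with an adjusted p under 0.05, a mean of at least 5 TPM in the higher group and no overlap of values, with numbered Gm and Rik symbols and pseudogenes passed over. It always took Cyr61, Fbxo32, Trim63, Mstn, Myh7, Myh2, Myh1 and Myh4, and up to 4 passing members of each called list in the direction of its call. Between models it took genes called in all 3, and up to 6 per interaction that were called in opposite directions in both; where no gene passed, it took the 6 with the smallest unadjusted p. Some genes that the rule took are not reported here. Myh7 stayed under the filter in all comparisons, with group means from 0.405 to 3.09 TPM.

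Alternatives were pseudocounts of 0.1 and 0.5, no filter, a filter of 5 TPM, median-of-ratios scaling, rescaling without mitochondrial genes and the top 20 genes, quantile normalization, all groups in 1 fit, robust variances, array weights, a replicate block, stricter thresholds (adjusted p under 0.01, or an absolute log2 change of at least 1) and leaving out each library in turn. Median-of-ratios factors used genes with a TPM of at least 1 in every library of the fit. limma voom on recovered reads, with total or scaled library sizes, and some combined alternatives were added after the data were seen. The other splits of each comparison were enumerated (35 for 4 against 4, 10 for 3 against 3, mirror splits taken as the same), and 100 random relabellings within the experiments were drawn for the interactions. The pipeline was tested on simulated data with 200 changed genes per comparison: limma recovered 34.3% (old), 41.8% (dexamethasone), 53.7% (LLC) and 44.8% (siRNA) of 1.5-fold changes, 76.1 to 89.6% of 2-fold and 97 to 100% of 4-fold changes. Each simulated gene was drawn on its own with a spread averaged over all groups, without variation shared by the genes of a library. The changed genes were not mitochondrially encoded and had a mean of at least 5 TPM. Loading and figures used Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.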

Results

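RNA of the tibialis anterior, a muscle at the front of the lower leg, was sequenced from male C57BL/6J mice in 30 libraries, which fall into 8 groups and 4 experiments. Muscle of mice aged 24 months (old, n = 3) stood beside muscle of mice aged 6 months (young, n = 3). Muscle after dexamethasone, a synthetic glucocorticoid, stood beside its own control (n = 4 each). Muscle under LLC cancer stood beside its own control (n = 4 each); the labels give only the abbreviation, which usually stands for Lewis lung carcinoma, a mouse tumour line. Muscle with an siRNA against Cyr61 stood beside muscle with NT siRNA (n = 4 each); Cyr61, also named Ccn1, encodes a secreted matrix protein, and NT is not spelled out in the labels. The series title concerns how molecular changes in muscle wasting differ with the stimulus, and the first 3 comparisons address that question.

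Expression was measured as TPM, and 23193 genes were above 0 in at least 1 library. The reads recovered from the TPM steps totalled 27.4e6 to 33.2e6 in the old libraries and 29.9e6 to 34.0e6 in the young. They totalled 45.7e6 to 55.0e6 in the dexamethasone libraries and 48.3e6 to 54.2e6 in their controls. LLC libraries held 42.8e6 to 46.5e6 and their controls 43.1e6 to 47.1e6. Cyr61 siRNA libraries held 36.9e6 to 40.8e6 and NT siRNA libraries 35.9e6 to 40.8e6. Mitochondrially encoded genes took 37.9 ± 3.2% (SD, n = 4) of TPM after dexamethasone against 48.7 ± 2.1% (SD, n = 4) in its control. They took 48.5 ± 4.2% (SD, n = 3) in old and 50.6 ± 2.3% (SD, n = 3) in young muscle. The share was 50.9 ± 6.5% (SD, n = 4) under LLC, with 60.4% in the library LLC 3, against 46.0 ± 3.0% (SD, n = 4) in the control. It was 48.8 ± 4.5% (SD, n = 4) with Cyr61 siRNA and 51.0 ± 4.5% (SD, n = 4) with NT siRNA. Since TPM of a library sums to a constant, a smaller share of these genes raises the TPM of all others. Means below are TPM ± SD over the libraries of a group, and an adjusted p comes from limma unless stated otherwise.

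**Figure D1:**
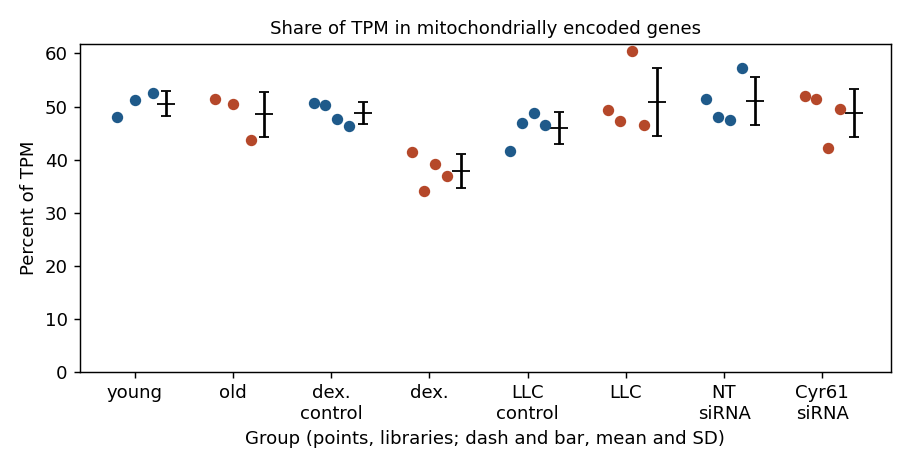
Percent of TPM in mitochondrially encoded genes for each library (points) of the 8 groups, with the mean and SD of each group (dash and bar). The dexamethasone group has a mean of 37.9%, and the means of the other groups lie between 46.0% and 51.0%.

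As fitted, old muscle held more transcript of a metallothionein, a peroxidase, a lipid carrier and a cytokine inhibitor than young muscle, and less of an imprinted noncoding RNA, but none of these calls held after median-of-ratios scaling or without the library young 3. Mt2, a metallothionein that binds zinc and copper, rose from 4.39 ± 1.03 TPM (n = 3) in young to 17.2 ± 6.30 TPM (n = 3) in old muscle (adjusted p = 0.00141). Gpx3, a secreted glutathione peroxidase, rose from 154 ± 10.5 to 282 ± 58.4 TPM (adjusted p = 0.0150), and Apod, a lipid-binding lipocalin, rose from 24.1 ± 6.16 to 58.1 ± 17.7 TPM (adjusted p = 0.0202). Socs3, a feedback inhibitor of IL-6-type cytokine signalling, rose from 0.835 ± 0.169 to 2.63 ± 0.125 TPM (adjusted p = 0.00949). The noncoding RNA H19 fell from 235 ± 42.5 to 130 ± 24.7 TPM (adjusted p = 0.0295). In each of these genes every old library lay on the same side of every young library, 3 against 3. The naming rule required this of the genes taken for the size of their change, so it is no separate support for them. After scaling the adjusted p was 0.0594 for Mt2 and Socs3, 0.0841 for Gpx3, 0.176 for Apod and 0.230 for H19.

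The median of all 10511 genes tested was 0.137 higher in old muscle on the log2 scale, and 0.005 higher after median-of-ratios scaling, so changes are given here relative to that median. The relative log2 change was 1.58 for Mt2, 1.08 for Apod, 0.71 for Gpx3, 0.85 for Socs3 and −0.99 for H19. Penk, the precursor of enkephalins, rose from 3.12 ± 0.709 to 7.05 ± 0.259 TPM, a relative change of 0.85 (adjusted p = 0.0202). Plekhb1 rose from 26 ± 2.86 to 48.8 ± 11.95 TPM, a relative change of 0.73 (adjusted p = 0.0393). Ighm, the constant region of the IgM heavy chain, rose from 25.1 ± 4.44 to 59.1 ± 10.7 TPM, a relative change of 1.06 (adjusted p = 0.00217). H2-Q7, an MHC class I gene, rose from 2.84 ± 0.247 to 8.26 ± 2.71 TPM (adjusted p = 0.0124), and Amy1, an amylase, from 18.6 ± 2.07 to 41.9 ± 2.39 TPM (adjusted p = 0.00128). RP23-455C13.7, a transcript named only by its clone, rose from 8.04 ± 2.08 to 18.1 ± 3.06 TPM (adjusted p = 0.0195). The values of Ighm, H2-Q7 and Amy1 are uncertain, since how reads shared with related genes were split is not given in the sources used here. Cyr61 was at 20.6 ± 2.92 TPM in old and 13.9 ± 0.802 TPM in young muscle and did not pass (adjusted p = 0.169; exact permutation p = 0.1, the smallest that 20 arrangements allow). The ubiquitin ligases of muscle atrophy did not pass either, with Fbxo32 at 99.8 ± 20.6 against 78.6 ± 28.5 TPM (adjusted p = 0.491) and Trim63 at 125 ± 24.3 against 117 ± 18.0 TPM (adjusted p = 0.805). The difference in Trim63 was 0.09 on the log2 scale and −0.05 relative to the median gene. The fast myosin Myh1 was at 2110 ± 333 against 2908 ± 188 TPM (adjusted p = 0.148), and Myh2, Myh4 and the growth inhibitor Mstn did not pass (adjusted p = 0.754, 0.592 and 0.697).

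Of 33 gene lists with enough members, camera at a preset correlation of 0.01 placed 10 above and 7 below the other genes. With an estimated correlation between genes 0 of the 17 calls held, the lowest adjusted p = 0.907 with an estimated correlation, and fry called 0 lists (lowest adjusted p = 0.657). The 8 Schwann cell genes tested had a median 0.41 above the median gene, the 9 tendon cell genes 0.34, the 23 interferon-stimulated genes 0.23 and the 13 macrophage genes 0.21. No gene of these 4 lists passed over all genes, while 6 of the Schwann cell, 6 of the tendon cell, 0 of the interferon-stimulated and 5 of the macrophage genes passed adjusted over the list alone. Also placed above were the 17 denervation and neuromuscular junction genes (median 0.20 above), the 13 genes of smooth muscle cells and pericytes (0.18; 2 passing adjusted over the list alone) and the 13 of the IL-6-type response (0.18; 3). So were the 16 YAP/TAZ targets (0.12; 1), the 18 endothelial genes (0.10; 0) and the 38 ribosomal protein genes (0.01; 0). Socs3 was the only member of these lists that passed over all genes, and the ribosomal protein median turned to −0.01 after scaling. Placed below were the mitochondrially encoded mRNAs (13 tested, median −0.20), nuclear-encoded oxidative phosphorylation (54, −0.20, with 53 under the median gene), collagens and extracellular matrix (24, −0.14), fatty acid oxidation (26, −0.13), glycolysis (20, −0.10), slow-fibre contractile genes (13, −0.08) and heat shock proteins (20, −0.06). None of their members passed over all genes, and 2 slow-fibre and 2 heat shock genes passed downward and 1 collagen and matrix gene upward adjusted over the list alone. Before the shift was taken off, the medians of collagens, fatty acid oxidation and glycolysis were 0.00, 0.01 and 0.04, and those of slow-fibre and heat shock genes 0.06 and 0.08 with means of −0.13 and −0.01, so median, mean and test differed in sign. Of the 10 splits of these libraries, 3 gave as many list calls.

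In all, limma called 18 genes, 16 higher and 2 lower, and 1174 genes (11.2%) had an unadjusted p under 0.05. After median-of-ratios scaling it called 0 genes, with 1391 at an unadjusted p under 0.05. The voom fit to recovered reads called 2 genes, and 0 with scaled library sizes (1367 and 1397 at an unadjusted p under 0.05). The groups did not overlap in 1706 genes (16.2%, where chance gives 10%). Leaving out the library young 3 left 0 called genes (513 at an unadjusted p under 0.05), with adjusted p of 0.0528 to 0.487 for the 11 genes described as passing. Without old 3, limma called 16 genes, and H2-Q7, Apod, RP23-455C13.7, Penk, Plekhb1 and H19 were at 0.0966 to 0.165. It called 114 genes without old 1, 179 without old 2, 274 without young 1 and 207 without young 2. In every such fit 2 lists stayed called, oxidative phosphorylation and the IL-6-type response. Of the other 15, 4 were lost without old 1 (adjusted p from 0.0570 to 0.35), 3 without old 2 (0.178 to 0.675), 7 without old 3 (0.0537 to 0.867), 3 without young 1 (0.213 to 0.969), 2 without young 2 (0.0756 and 0.720) and 5 without young 3 (0.117 to 0.991).

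After dexamethasone, acute-phase genes such as Lcn2 rose many-fold, while Retnla, Iigp1 and Igkc were among the genes that fell. Lcn2, a lipocalin that binds bacterial iron carriers, rose from 0.653 ± 0.170 TPM (n = 4) in the control to 106.5 ± 24.8 TPM (n = 4), a log2 change of 6.00 (SE 0.17, adjusted p = 3.69e-08). Spp1, the secreted phosphoprotein osteopontin, rose from 19.4 ± 6.98 to 531.5 ± 277 TPM (adjusted p = 0.00018). Pnmt, the enzyme that turns noradrenaline into adrenaline, rose from 1.57 ± 0.170 to 51.9 ± 16.5 TPM (adjusted p = 1.89e-06), and Sln, a small inhibitor of the calcium pump of muscle, from 37.3 ± 11.4 to 349 ± 189 TPM (adjusted p = 0.00104). Retnla, a secreted protein of macrophages and other cells, fell from 166 ± 67.6 to 2.35 ± 1.41 TPM (adjusted p = 1.96e-05).

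The median of all 11944 genes tested was 0.329 higher after dexamethasone on the log2 scale and 0.016 higher after median-of-ratios scaling, and changes from here on in this comparison are relative to that median. Of all genes tested 4290 were called higher and 180 lower, and after scaling 530 and 563. The counts of list members below are to be read beside these. The relative change was 5.67 for Lcn2, 4.28 for Spp1, 3.98 for Pnmt, 2.75 for Sln and −5.99 for Retnla. Other large increases were Gnmt, which methylates glycine (3.19), Orm1, an acute-phase plasma protein (3.18), S100a8, a calcium-binding protein of neutrophils (2.86), Mt2 (2.58), Clec4n, a receptor for fungal sugars (2.29), and Gpnmb, a membrane glycoprotein of macrophages (2.28). Other large decreases were Retnlg (−3.42), the interferon-inducible GTPases Iigp1 (−3.22) and Tgtp2 (−2.56), the antibody light chain Igkc (−3.13), Col6a5, a chain of collagen VI (−3.06), Ear2, an eosinophil ribonuclease (−2.93), the chemokines Cxcl9 (−2.83) and Ccl8 (−2.80), and H2-Eb1, an MHC class II chain (−2.53). In each of these 20 genes the 4 treated libraries lay apart from the 4 controls, which the naming rule required and which is no separate support. Each passed after scaling too. How reads shared with related genes were split is not given, so the values of Orm1, Ear2, Igkc, Iigp1 and Tgtp2 are uncertain.

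The lists of immune genes moved apart. Of 26 interferon-stimulated genes 18 fell, 22 adjusted over the list alone and 23 after scaling, with a median of −1.12. Irf7, a transcription factor of the interferon response, fell from 10.2 ± 3.37 to 3.17 ± 0.83 TPM (−1.71), Gbp3, a guanylate-binding protein, by a relative −1.55, and Psmb9, a subunit of the immunoproteasome, by a relative −1.25. The interferon list had an adjusted p = 0.0961 with an estimated correlation. All 3 lymphocyte genes tested fell, 3 adjusted over the list alone and 3 after scaling: Igkc, the chemokine Ccl5 (−1.73) and Ighm (−1.51, from 40.6 ± 10.3 to 17.4 ± 4.92 TPM). This call held with an estimated correlation (adjusted p = 0.00816 with an estimated correlation). Of 19 genes of the IL-6-type and acute-phase response 14 rose, 16 adjusted over the list alone and 6 after scaling, with a median of 0.54; besides Lcn2 and Orm1 they included Serpina3n, a protease inhibitor (2.26), and Lrg1, a plasma glycoprotein (1.37). That list had an adjusted p = 0.414 with an estimated correlation. All 18 macrophage genes tested rose, 18 adjusted over the list alone, with a median of 0.70, and 5 of them passed after scaling (adjusted p = 0.578 with an estimated correlation). Among them the lysozyme Lyz2 rose from 239 ± 63.2 to 1255 ± 562 TPM (1.99), the lysosomal protein Cd68 from 20.8 ± 6.22 to 67.0 ± 20.5 TPM (1.31), the endotoxin co-receptor Cd14 by a relative 1.42 and the haemoglobin scavenger receptor Cd163 by a relative 1.02. Lyz2 shares much of its sequence with Lyz1. Of the 18 endothelial genes 0 rose and 1 fell, Cldn5, a tight junction protein (−0.67), 0 adjusted over the list alone, while 9 fell after scaling, and the median was −0.36 (adjusted p = 0.406 with an estimated correlation). Cldn5 lost its call without dexamethasone control 1, 2 or 3 or dexamethasone 3 (adjusted p = 0.103, 0.0805, 0.0717 and 0.0733).

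Genes of protein turnover and protein folding rose in libraries whose mitochondrial share was 37.9% against 48.7% in the control. Of 31 proteasome subunits 29 rose, 31 adjusted over the list alone, with a median of 0.14 above the median gene (adjusted p = 0.414 with an estimated correlation). Psmd8 rose from 92.0 ± 10.3 to 163 ± 9.28 TPM (0.49), Psmd2 from 99.5 ± 5.34 to 159 ± 13.0 TPM (0.34), Psmd4 by a relative 0.28 and Psmc5 by a relative 0.20, but 0 subunits passed after scaling. Of 30 autophagy and lysosome genes 19 rose, 21 adjusted over the list alone, with a median of 0.14 (adjusted p = 0.578 with an estimated correlation). The lysosomal protease Ctsl rose from 126 ± 11.1 to 300.2 ± 44.4 TPM (0.91) and was the member that passed after scaling, while Ctsd rose by a relative 0.49, the autophagosome protein Map1lc3a by 0.54 and the mitophagy receptor Bnip3 by 0.23. Of 21 genes of the unfolded protein response 19 rose, 20 adjusted over the list alone, with a median of 0.38 and 4 passing after scaling (adjusted p = 0.528 with an estimated correlation). They included the chaperones Calr, from 79.5 ± 8.46 to 153 ± 21.8 TPM (0.60), Hspa5, from 61.1 ± 2.28 to 117 ± 21.7 TPM (0.57), and Dnajb11 (0.34), and the transcription factor Xbp1 (0.38). Of 38 ribosomal protein genes 36 rose, 38 adjusted over the list alone, with a median of 0.23 and 0 passing after scaling (adjusted p = 0.72 with an estimated correlation); Rpl10 changed by a relative 0.49, Rpl14 by 0.36, Rpl4 by 0.30 and Rpl8 by 0.26, with reads shared among pseudogenes. Of 20 heat shock genes 16 rose, 18 adjusted over the list alone, with a median of 0.22 and 2 passing after scaling, Hsp90ab1 (0.48) and Hsph1 (0.51), beside Hspa4 (0.23) and Cryab (0.43) before it (adjusted p = 0.654 with an estimated correlation). Without dexamethasone 1 the ribosomal list was at an adjusted p of 0.873 and the heat shock list at 0.0930.

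Genes of denervation and myogenesis rose, and mitochondrially encoded mRNAs fell. Of 23 denervation and neuromuscular junction genes 16 rose, 19 adjusted over the list alone, with a median of 0.84, and after scaling 12 rose and 2 fell (adjusted p = 0.484 with an estimated correlation). Chrnd, a subunit of the acetylcholine receptor, rose from 4.03 ± 0.661 to 12.7 ± 2.53 TPM (1.10), the adhesion molecule Ncam1 from 3.46 ± 1.29 to 13.8 ± 2.88 TPM (1.42) and the transcription factor Runx1 by a relative 1.09. Of 15 satellite cell and myogenesis genes 10 rose, 10 adjusted over the list alone and 6 after scaling, with a median of 0.32 (adjusted p = 0.611 with an estimated correlation). The myogenic regulator Myog rose from 22.8 ± 7.44 to 72.0 ± 16.7 TPM (1.32), the fusion proteins Tmem8c (1.71) and Gm7325 (1.31) and the cadherin Cdh15 (0.62) rose too, and without dexamethasone 1 the list was at an adjusted p of 0.0984. Of 13 mitochondrially encoded mRNAs 6 fell, 11 adjusted over the list alone and 5 after scaling, with a median of −0.67, and this call held with an estimated correlation (adjusted p = 0.00816 with an estimated correlation). The cytochrome oxidase subunit mt-Co1 fell from 81260 ± 4065 to 58400 ± 7863 TPM (−0.81), and mt-Nd1 (−0.71), mt-Atp8 (−0.74) and mt-Nd2 (−0.64) fell as well; after scaling mt-Co1 and mt-Nd1 were at an adjusted p of 0.0573 and 0.0539. Of 54 nuclear-encoded oxidative phosphorylation genes 1 fell, Cox7a1 (−0.71), 0 adjusted over the list alone and 5 after scaling, and all 54 lay under the median gene with a median of −0.35 (adjusted p = 0.406 with an estimated correlation). Of 20 glycolysis genes 2 fell, the glycolytic enzymes Pgam2 (−0.78) and Pkm (−0.58), 0 adjusted over the list alone and 3 after scaling, with a median of −0.41 (adjusted p = 0.207 with an estimated correlation); before the shift was taken off, the median was −0.08 and the mean 0.03. Without dexamethasone control 1, 2, 3 or 4, 7, 6, 4 and 6 of these 7 genes missed the threshold (adjusted p up to 0.130, 0.113, 0.0837 and 0.113), and without dexamethasone 2, 3 or 4, 1, 2 and 5 did (up to 0.0503, 0.0785 and 0.0836).

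The lists of fast-fibre contractile genes, fibroadipogenic progenitors and tendon cells were placed below the other genes while members went both ways. Of 17 fast-fibre genes 3 rose and 0 fell, 3 adjusted over the list alone, with a median of −0.18 relative to the median gene and 0.15 before the shift was taken off (adjusted p = 0.528 with an estimated correlation); after scaling 0 rose and 2 fell. The 3 were the contractility regulator Smtnl1 (0.52) and the Z-disc proteins Myoz1 (0.23) and Actn3 (0.51), and the 2 were Tpm1 and Casq1, all chosen after their values were seen. Of 16 progenitor genes 4 rose and 2 fell, Clec3b (−0.71) and Cd34 (−0.68), with Gsn, Fbn1, Hic1 and Smoc2 (chosen after their values were seen) rising. Adjusted over the list alone 4 rose and 2 fell, and after scaling 0 rose and 2 fell, with a relative median of −0.14 and 0.19 before the shift was taken off (adjusted p = 0.696 with an estimated correlation). Of 12 tendon cell genes 4 rose and 2 fell, the matrix protein Kera (−1.61) and the membrane protein Tnmd (−1.35), with Prg4 (2.22), Tnc (1.97), Scx (1.41) and Comp (0.38; chosen after their values were seen) rising. Adjusted over the list alone 5 rose and 2 fell, and after scaling 3 rose and 2 fell, with a relative median of −0.22, while the mean before the shift was taken off was 0.39 (adjusted p = 0.578 with an estimated correlation). The fast-fibre list lost its call without dexamethasone 2 (adjusted p = 0.0694) or dexamethasone 3 (0.130). The progenitor list lost its call without dexamethasone control 1 (0.0778) or 3 (0.130) or dexamethasone 2 (0.197) or 4 (0.0777). Cd34 missed the threshold in all 8 fits without 1 library (adjusted p from 0.0504 to 0.124) and Clec3b without dexamethasone control 1, 3 or 4 or dexamethasone 3 or 4 (0.0848, 0.0760, 0.0807, 0.0595 and 0.0555). The myosins Myh2 (198 ± 103 against 167 ± 48.3 TPM), Myh1 (3514 ± 786 against 3132 ± 310.0 TPM) and Myh4 (11970 ± 5270 against 9695 ± 1633 TPM) did not pass, and their differences changed sign under scaling, to −0.22, −0.22 and −0.14.

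Cyr61, at position 145646976 to 145649981 of chromosome 3 in mm10, rose from 21.1 ± 2.56 to 47.5 ± 16.1 TPM after dexamethasone, a log2 change of 1.09 (SE 0.20) and 0.76 relative to the median (adjusted p = 0.0047; 0.0194 after scaling). Every treated library lay above every control, and the exact permutation p of 0.0286 is the smallest that 70 arrangements allow. Fbxo32 rose from 61.8 ± 8.51 to 117 ± 48.6 TPM (0.51, adjusted p = 0.0188) and Trim63 from 110 ± 16.8 to 228 ± 104 TPM (0.61, adjusted p = 0.0240). Neither passed after scaling (adjusted p = 0.183 and 0.198), and Fbxo32 was at 0.0509 without dexamethasone control 4, while Trim63 was at 0.0680 without dexamethasone control 1 and 0.0546 without dexamethasone control 4. Mstn, at 19.4 ± 2.96 against 14.0 ± 2.29 TPM (0.11, adjusted p = 0.0405), was at 0.685 after scaling and passed without dexamethasone control 2 and without dexamethasone 1, but in none of the other 6 fits without 1 library (0.0757 to 0.120). Of 22 glucocorticoid receptor targets 10 rose, 11 adjusted over the list alone and 5 after scaling, and camera did not call the list (adjusted p = 0.714). Of 27 atrophy ligases and regulators 12 rose, 12 adjusted over the list alone and 3 after scaling, and camera did not call that list either (adjusted p = 0.378). Over all genes 4290 of 11944 rose, so the counts as fitted do not by themselves set either list apart.

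**Figure D2:**
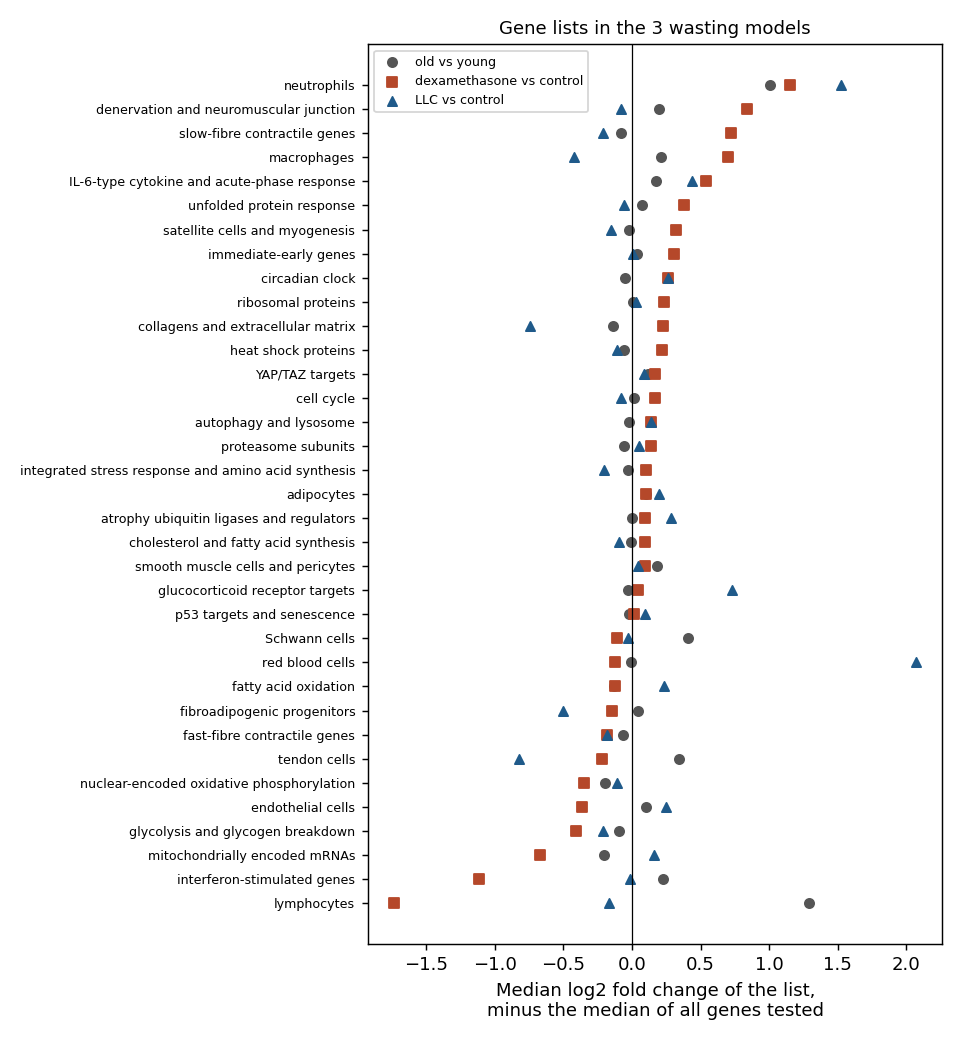
Median log2 fold change of each gene list minus the median of all genes tested (x axis) for old against young, dexamethasone against control and LLC against control (markers). After dexamethasone the macrophage list lies at 0.70 and the interferon-stimulated genes at −1.12.

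In all, limma called 4470 genes after dexamethasone, 4290 higher and 180 lower (96% higher), and 285 and 58 of them changed at least 2-fold. After scaling it called 530 higher and 563 lower (48.5% higher), 708 genes being called in both fits with 0 changing direction, and 110 and 93 changed at least 2-fold. The groups did not overlap in 4294 genes (36%, where chance gives 2.9%). The count was 2007 without dexamethasone control 1, 1918 without control 2, 2525 without control 4, 8715 without dexamethasone 1, 2740 without dexamethasone 3 and 2549 without dexamethasone 4. Of the 75 named genes that passed, 62 passed in every fit without 1 library. The other 13 are named above, of which 12, 8, 8 and 11 missed the threshold without dexamethasone control 1, 2, 3 and 4 and 1, 3, 6 and 8 without dexamethasone 1, 2, 3 and 4 (adjusted p up to 0.130 in all). In all, camera called 18 of 35 lists, 9 above and 9 below the other genes, of which 2 held with an estimated correlation. After scaling the proteasome, fast-fibre, progenitor and tendon cell lists were not called (adjusted p = 0.0680, 0.0595, 0.0816 and 0.721). The fry test called 24, and 13 of the 18 stayed called without any 1 library; 8 of the 35 splits of these libraries gave as many list calls.

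Under LLC cancer, 2 glucocorticoid receptor targets, Arrdc2 and Foxo1, rose, while chains of collagen VI, tendon proteins and transcripts such as Cited4 and Mettl21c fell. Arrdc2, an arrestin-domain adaptor protein, rose from 17.3 ± 8.05 TPM (n = 4) in the control to 62.3 ± 18.8 TPM (n = 4), a log2 change of 1.84 (SE 0.26, adjusted p = 0.0107). Fmo2, a flavin monooxygenase, rose from 4.23 ± 0.402 to 12.6 ± 2.23 TPM (1.37, adjusted p = 0.00122), and Mid1ip1, a regulator of fatty acid synthesis, from 23.1 ± 4.46 to 52.5 ± 6.89 TPM (1.16, adjusted p = 0.00926). Cited4, a transcriptional co-activator, fell from 16.4 ± 1.92 to 4.16 ± 1.21 TPM (−1.78, adjusted p = 0.00122). Mettl21c, a lysine methyltransferase of muscle, fell from 28.8 ± 5.79 to 7.73 ± 2.60 TPM (−1.79, adjusted p = 0.00428), and Smox, which oxidises spermine, from 231 ± 32.6 to 76.9 ± 20.5 TPM (−1.61, adjusted p = 0.00616). In each of these genes the 4 LLC libraries lay apart from the 4 controls, which the naming rule required and which is no separate support.

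The median of the 10830 genes tested was −0.051 and −0.008 after scaling, so log2 changes are given as fitted. Foxo1, a transcription factor that drives atrophy genes, rose from 2.59 ± 0.311 to 6.60 ± 2.23 TPM (1.03, adjusted p = 0.0362), and Tbc1d4, which governs glucose transporter traffic, rose by 0.83 (adjusted p = 0.0352). Cep85l (1.64), Galnt15, a glycosyltransferase (1.03), Acss1, a mitochondrial acetyl-CoA synthetase (0.91), the noncoding RNA Malat1 (0.88) and Gda, a guanine deaminase (0.87), rose with adjusted p from 0.0201 to 0.0493. Nmrk2, a nicotinamide riboside kinase of muscle, fell from 254 ± 30.5 to 76.2 ± 47.3 TPM (−1.88, adjusted p = 0.0169). Ighm fell from 52.9 ± 10.3 to 18.2 ± 4.35 TPM (−1.50, adjusted p = 0.00611), and Erdr1 (−1.54), Nrep (−1.47), Kera (−1.43) and the carbonyl reductase Cbr2 (−1.35) fell with adjusted p from 0.0149 to 0.0250.

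Of 27 collagen and extracellular matrix genes 5 fell, 14 adjusted over the list alone, with a median of −0.80 and 7 passing after scaling (adjusted p = 0.712 with an estimated correlation). They included the collagen VI chains Col6a2, from 13.5 ± 1.97 to 4.75 ± 1.60 TPM (−1.37, adjusted p = 0.0107), Col6a1, from 27.6 ± 4.12 to 11.75 ± 4.18 TPM (−1.22), Col6a3 (−1.07), the collagen V chain Col5a1 (−1.21) and Col15a1 (−0.80; chosen after its values were seen). Of 10 tendon cell genes 3 fell, 6 adjusted over the list alone and 2 after scaling, with a median of −0.87 (adjusted p = 0.395 with an estimated correlation): Kera, Tnmd (−1.28) and Col22a1 (−0.60), the last at an adjusted p of 0.0851 after scaling. Of 15 fibroadipogenic progenitor genes 1 fell, Clec3b (−1.16), 6 adjusted over the list alone and 2 after scaling, with a median of −0.55 (adjusted p = 0.712 with an estimated correlation). Of 17 fast-fibre genes 1 fell, 2 adjusted over the list alone and 2 after scaling (adjusted p = 0.712 with an estimated correlation): Myl1, an alkali light chain of fast myosin, from 8519 ± 241 to 5438 ± 255 TPM (−0.65, adjusted p = 0.0201). The 20 glycolysis genes had a median of −0.26 with 0 passing, 6 adjusted over the list alone (adjusted p = 0.712 with an estimated correlation). The 54 oxidative phosphorylation genes had a median of −0.16 and the 17 macrophage genes −0.47, with 0 passing in either, 0 adjusted over the list alone in either (adjusted p = 0.889 with an estimated correlation in both). The oxidative phosphorylation list lost its call without LLC control 1 (adjusted p = 0.314), LLC 2 (0.748) or LLC 4 (0.131), and the macrophage list without LLC control 2 (0.278), LLC 3 (0.349) or LLC 4 (0.0977).

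Of 22 glucocorticoid receptor targets 2 rose, Arrdc2 and Foxo1, 9 adjusted over the list alone, with a median of 0.68 and 7 passing after scaling (adjusted p = 0.395 with an estimated correlation). Fkbp5, a co-chaperone of the glucocorticoid receptor chosen after its values were seen, was at 26.3 ± 12.9 against 6.94 ± 1.29 TPM and did not pass (adjusted p = 0.0799). After scaling Fkbp5 was called higher both under LLC (log2 change 1.63) and after dexamethasone (1.04). Of 27 atrophy ligases and regulators 1 rose, Foxo1, 4 adjusted over the list alone and 4 after scaling, with a median of 0.23 (adjusted p = 0.712 with an estimated correlation). Of 5 neutrophil genes 1 rose, the growth factor receptor Csf3r (0.94, from 0.505 ± 0.205 to 1.96 ± 0.850 TPM), 4 adjusted over the list alone, with a median of 1.47 (adjusted p = 0.395 with an estimated correlation). Of 17 genes of the IL-6-type response 1 rose, the oncostatin M receptor Osmr (0.92), 2 adjusted over the list alone and 2 after scaling (adjusted p = 0.712 with an estimated correlation). The 8 red blood cell genes had a median of 2.02 with 0 passing, 5 adjusted over the list alone (adjusted p = 0.712 with an estimated correlation). Hbb-bs, a haemoglobin chain chosen after its values were seen, was at 1716 ± 1295 against 296 ± 35 TPM (adjusted p = 0.0909), and globin genes share reads. Of 17 circadian clock genes 0 rose and 1 fell, Bhlhe41, a repressor of the clock chosen after its values were seen (−0.94, adjusted p = 0.0114), 6 upward and 4 downward adjusted over the list alone, and 5 upward and 1 downward after scaling (adjusted p = 0.712 with an estimated correlation). Placed above the other genes with 0 members passing were the 18 endothelial genes (median 0.20; 4 upward and 1 downward adjusted over the list alone, 4 upward after scaling; adjusted p = 0.712 with an estimated correlation), the 27 fatty acid oxidation genes (0.18; 1, and 1 after scaling; adjusted p = 0.737 with an estimated correlation). So were the 30 autophagy and lysosome genes (0.09; 1, and 3 after scaling; adjusted p = 0.737 with an estimated correlation) and the 13 mitochondrially encoded mRNAs (0.11; 0; adjusted p = 0.712 with an estimated correlation). The mitochondrial list was at an adjusted p of 0.621 without LLC 3, the library with a mitochondrial share of 60.4%.

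Cyr61 was at 26.7 ± 11.7 TPM under LLC and 19.5 ± 2.79 TPM in the control and did not pass (adjusted p = 0.701; exact permutation p = 0.429, of 70 arrangements that allow no less than 0.0286). Fbxo32 (126 ± 65.4 against 79.5 ± 15.4 TPM, adjusted p = 0.596), Trim63 (186 ± 74.6 against 132 ± 10.6 TPM, adjusted p = 0.606), Mstn (adjusted p = 0.640), Myh2 (0.868), Myh1 (0.925) and Myh4 (7324 ± 1872 against 9449 ± 462 TPM, adjusted p = 0.325) did not pass either. In all, limma called 128 genes, 32 higher and 96 lower (25% higher), with 1429 (13.2%) at an unadjusted p under 0.05. After scaling it called 181 higher and 170 lower (51.6% higher), 120 genes being called in both fits. The voom fit called 126 higher and 136 lower, or 230 and 176 with scaled library sizes. The groups did not overlap in 826 genes (7.6%, where chance gives 2.9%). The count was 361 (226 higher and 135 lower) without LLC 3, 20 without LLC 1 and 59 without LLC 4, and 51, 48, 51 and 19 without LLC control 1, 2, 3 and 4. Of the 29 named genes that passed, Arrdc2, Fmo2, Mid1ip1, Mettl21c, Cited4, Smox, Ighm and Col6a2 passed in every fit without 1 library. The other 21 were lost without LLC control 4 (adjusted p from 0.0539 to 0.141) and without LLC 1 (0.0574 to 0.140). Of them, 14, 15, 10, 3 and 10 were lost without LLC control 1 (up to 0.118), LLC control 2 (up to 0.118), LLC control 3 (up to 0.118), LLC 2 (up to 0.0751) and LLC 4 (up to 0.0984). In all, camera called 17 of 35 lists, 10 above and 7 below the other genes, of which 0 held with an estimated correlation. The fry test called 0 (lowest adjusted p = 0.128), and 8 of the 35 splits of these libraries gave as many list calls.

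With the siRNA against Cyr61, Cyr61 itself was at 32.9, 52.8, 45.8 and 25.5 TPM in the 4 libraries, against 57.0, 64.6, 67.8 and 36.8 TPM with NT siRNA. The mean was 39.2 ± 12.3 TPM (n = 4) against 56.6 ± 13.9 TPM (n = 4), a difference of −30.6% and of −0.53 on the log2 scale (SE 0.25). The ranges overlapped, and the difference did not pass an exact permutation test (p = 0.143 of 70 arrangements, the smallest possible being 0.0286; adjusted p = 0.999 in limma). Neither test used the replicate numbers, and whether these pair the samples is unsettled. In the order given, each Cyr61 siRNA value lay below its NT siRNA counterpart. Between 1133 and 2888 reads lay behind each value of Cyr61, so counting error was small beside the spread between libraries. No other gene passed, and Fbxo32 was at 245 ± 75.6 against 225 ± 92.1 TPM and Trim63 at 361 ± 130 against 320 ± 161 TPM.

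**Figure D3:**
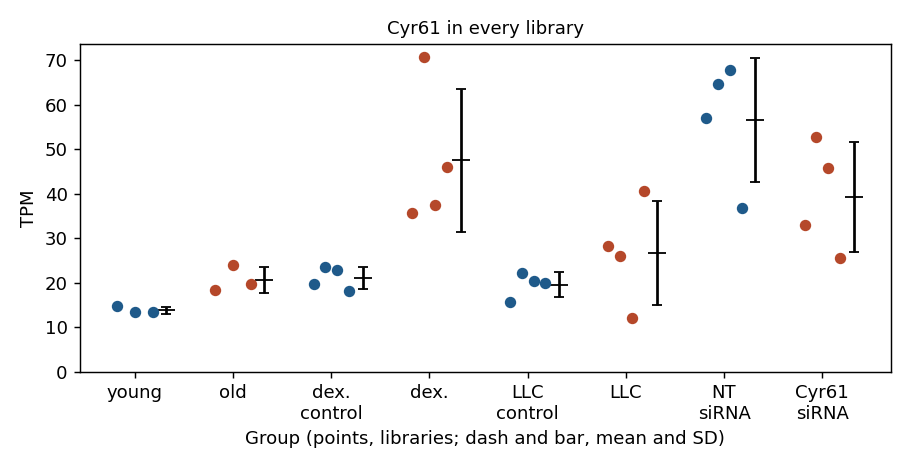
TPM of Cyr61 in every library (points) of the 8 groups, with the mean and SD of each group (dash and bar). The dexamethasone libraries lie above their controls, while the Cyr61 siRNA and NT siRNA libraries overlap.

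This comparison asks which transcripts of muscle follow Cyr61. Since the lower Cyr61 itself did not pass either test, a working knockdown is not shown, and a lack of called genes cannot answer that question. The 6 genes with the smallest unadjusted p were Sec23a, of the coat of transport vesicles (21.4 ± 1.55 against 28.5 ± 3.09 TPM), Eif4ebp2, a repressor of translation (55.95 ± 6.40 against 41.9 ± 5.06 TPM), and 4 others. These were Tnnt1, the slow troponin T (7.70 ± 3.15 against 14.6 ± 4.09 TPM), Parp6 (16.4 ± 0.195 against 13.6 ± 0.677 TPM), Bex1 (18.9 ± 5.98 against 11.3 ± 2.43 TPM) and Rnaseh1 (7.07 ± 0.137 against 5.81 ± 0.383 TPM), each at an adjusted p of 0.999. Mstn, Myh2, Myh1 and Myh4 did not pass either (adjusted p = 0.999). limma called 0 of 11006 genes, with 109 (1.0%) at an unadjusted p under 0.05, which is fewer than that threshold gives by chance among independent genes. The voom fit called 0 with 162, or 168 with scaled library sizes. The groups did not overlap in 109 genes (1%, where chance gives 2.9%). With the replicate block limma called 0 genes, with 634 at an unadjusted p under 0.05. Without the fourth library of both groups, an alternative chosen after the data were seen, limma called 0 genes, with 155 at an unadjusted p under 0.05. On simulated data of this size limma recovered 44.8% of genes changed 1.5-fold, 89.6% changed 2-fold and 97% changed 4-fold. The simulation drew each gene on its own with a spread averaged over all groups, so variation shared by genes of a library was left out. Recovery in the real libraries may therefore be lower.

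Gene lists were nevertheless called by camera at the preset correlation, with no member passing over all genes or adjusted over the list alone. With an estimated correlation 0 of the 15 calls held, and fry called 0 lists (lowest adjusted p = 0.937). The proteasome list lay highest by its test, with 30 of 31 subunits above the median gene (adjusted p = 0.784 with an estimated correlation). The unfolded protein response (0.897), endothelial (0.784), smooth muscle and pericyte (0.784), Schwann cell (0.628) and tendon cell (0.784) lists were above too, each p being the adjusted p with an estimated correlation. Of oxidative phosphorylation genes 53 of 54 lay under the median gene (adjusted p = 0.784 with an estimated correlation). The mitochondrially encoded mRNAs (0.784), fatty acid oxidation (0.784), slow-fibre (0.554), satellite cell (0.784), macrophage (0.784), lymphocyte (0.784), red blood cell (0.784) and collagen (0.897) lists were below, with the same p given in brackets. Median and mean went apart for collagens (−0.02 and 0.02) and satellite cell genes (0.06 and −0.11). Of the 35 splits of these libraries, 20 gave as many calls. The proteasome, oxidative phosphorylation, slow-fibre and Schwann cell lists stayed called without any 1 library. Of the other 11, 6 were lost without Cyr61 siRNA 1 (adjusted p up to 0.760), 6 without Cyr61 siRNA 2 (up to 0.175), 5 without Cyr61 siRNA 3 (up to 0.642), and 4 without Cyr61 siRNA 4 (up to 0.459). Further, 6 were lost without NT siRNA 1 (up to 0.475), 6 without NT siRNA 2 (up to 0.815), 4 without NT siRNA 3 (up to 0.893) and 4 without NT siRNA 4 (up to 0.464).

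Across the 3 wasting models, more genes were called lower both under LLC and after dexamethasone than Fisher's exact test gives by chance. Genes called in opposite directions under LLC and after dexamethasone did not exceed chance in any test. Among 10738 genes tested in both, 18 fell in both where 1.3 would by chance (Fisher's exact test, adjusted p = 9.98e-15 over 24 tests), and 37 did after scaling where 7.93 would (adjusted p = 4.01e-14). Fisher's test takes genes as independent draws, which genes regulated together are not. Its p therefore does not measure the spread between libraries, here or in the overlaps below. Cited4, Mettl21c, Ighm, Nrep, Kera, Tnmd, Clec3b and Amd1, an enzyme of polyamine synthesis chosen after its values were seen, were among the 18. Fmo2, Galnt15, Mid1ip1 and Ifitm1, an interferon-inducible membrane protein chosen after its values were seen, rose in both, 4 genes where 10.35 would by chance (Fisher's exact test, p = 0.0116, adjusted p = 0.0698). After scaling 15 rose in both where 6.25 would (adjusted p = 0.0180), so that this overlap changed from below to above chance. Another 11 genes fell under LLC and rose after dexamethasone where 33.54 would (adjusted p = 2.33e-06; 4 after scaling where 5.9 would, adjusted p = 1), and 1, the adhesion molecule Selp, chosen after its values were seen, rose under LLC and fell after dexamethasone where 0.4 would (adjusted p = 1; 10 after scaling where 8.4 would, adjusted p = 1).

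The difference of the responses was tested as an interaction over 12392 genes in 22 libraries. The responses to LLC and dexamethasone differed in 3416 genes, 135 higher and 3281 lower under LLC, with a median difference of −0.37; after scaling they differed in 812 genes, 354 higher and 458 lower, 583 in both fits. Col6a3 changed by −1.07 under LLC and by 1.08 after dexamethasone (difference −2.15, adjusted p = 0.00029), the early growth response factor Egr1 by −1.18 and 0.77 (difference −1.94), Lyz1 by −0.94 and 1.24 (difference −2.18), Kdelr3, a receptor that returns proteins to the endoplasmic reticulum, by −0.90 and 0.75, and the secretory kinase Fam20c by −0.70 and 0.57 (difference −1.27). These differences passed after scaling too, but only Egr1 and Lyz1 kept their calls in both models, since Col6a3, Kdelr3 and Fam20c did not pass after dexamethasone (adjusted p = 0.0686, 0.271 and 0.189 after scaling). The genes named here were taken for opposite calls in the same libraries, so the p of their difference is no separate support. Lyz1 shares much of its sequence with Lyz2.

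Dexamethasone and old age shared 4 increases among 10458 genes, Apod, Gpx3, Mt2 and Socs3, where 4.94 would by chance (Fisher's exact test, p = 0.782, adjusted p = 1). Another 4 genes fell after dexamethasone and rose with age where 0.18 would by chance (adjusted p = 0.000181): the chemokine Ccl8, H2-Q7, Ighm and the protease inhibitor Spint2. After scaling the overlap was 0, since no gene was called in old muscle. Ccl8 changed by −2.47 after dexamethasone and by 1.75 with age (difference −4.22, adjusted p = 0.000831), H2-Q7 by −1.86 and 1.23 (difference −3.09, adjusted p = 5.24e-06), Ighm by −1.18 and 1.20 (difference −2.38) and Spint2 by −0.78 and 1.11 (difference −1.89). H19 changed by 0.89 and −0.85 (difference 1.74, adjusted p = 0.0217, and 0.0669 after scaling). These genes too were taken for opposite calls in the same libraries, so the p of their difference is no separate support. In all, the responses to dexamethasone and age differed in 255 genes, 161 higher and 94 lower after dexamethasone, and after scaling in 362, 100 higher and 262 lower, 173 in both fits. Relabelling the libraries within experiments gave as many as 255 genes in 7 of 101 labellings. Some of these labellings held the dexamethasone contrast itself, turned or as labelled. The share therefore did not exclude chance for this count and cannot decide about it.

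LLC and old age shared 0 genes called in the same direction among 10353 by limma, and 1 called in opposite directions, Ighm (1429 and 1174 genes had an unadjusted p under 0.05), and their responses differed in 6 genes, or in 28 after scaling, 5 of them in both fits. Ighm fell under LLC and rose with age, by −1.50 and 1.20 (difference −2.70, adjusted p = 0.000138). It was taken for these opposite calls in the same libraries, so this p is no separate support. No gene was called in the same direction in all 3 models, of 10343 tested in all 3, nor after scaling. The 6 genes with the smallest p in all 3 were Irf5, an interferon regulatory factor (log2 changes of −0.88 with age, −0.42 after dexamethasone and −0.94 under LLC), S100a9 (1.15, 1.49 and 3.13), and 4 others. They were Fmo2 (0.51, 0.77 and 1.37), Galnt15 (0.64, 0.52 and 1.03), the glutathione transferase Gstm7 (0.69, 0.63 and 0.47) and the ubiquitin ligase Sh3rf2 (0.58, 1.01 and 1.00). Across genes, which are not independent replicates, Pearson's r between the changes was 0.14 for LLC and dexamethasone (Spearman's rho 0.184), 0.181 for LLC and age (0.253) and 0.153 for dexamethasone and age (0.243). The Cyr61 siRNA shared 0 called genes with any model, since limma and voom called 0 genes for it; r across genes was 0.005 with LLC, 0.174 with dexamethasone and 0.145 with age (6 pairs in all).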

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

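The tests of explanations in this part were chosen after the results were seen; the counts over other splits were planned, but what they would show was written after.

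After dexamethasone 96% of the called genes were higher, a lopsided split that the mitochondrial share may produce, since TPM of a library sums to a constant. With mitochondrially encoded genes left out and the rest rescaled, the median of all genes dropped from 0.329 to 0.101, and limma called 985 genes, 656 higher and 329 lower (66.6% higher). Most of the shift was therefore gone, but not all, so the smaller mitochondrial share stays open as its source, and a true rise of many transcripts stays open beside it, untested. Shallow sampling of low genes is argued against, since 97.2% of the calls among genes with a mean of at least 10 TPM were higher.

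The library LLC 3, with a mitochondrial share of 60.4%, differed from the other LLC libraries, and 361 genes were called without it against 128 with it. Over the genes called without it, its median place between the control mean (0) and the mean of the other LLC libraries (1) was 0.6 after scaling (quartiles 0.28 and 0.89). Control libraries, placed in the same way, lay at 0.02 to 0.24 and the other LLC libraries at 0.78 to 0.95, which argues against a control sample labelled LLC. With TPM as deposited its place was 0.4, so the mitochondrial share could account for part of the distance and is not excluded as part of it. A milder response of that sample under LLC stays open and was not tested.

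After dexamethasone all 18 macrophage genes rose while 0 of 18 endothelial genes did; after scaling 5 macrophage genes rose and 9 endothelial genes fell. A smaller share of fibre RNA alone would raise the markers of both cell types alike, but their medians lay 1.06 apart (quartiles 0.64 and 1 for macrophage genes, −0.42 and −0.25 for endothelial genes, relative to the median gene). This argues against a smaller fibre share as the whole source. It cannot exclude that share as part of the macrophage rise, since endothelial transcripts may have changed for another reason. The smaller mitochondrial share is argued against as the whole source, since the macrophage median stayed at 0.67 after scaling. A candidate explanation that stays open is more macrophages, or more of these transcripts in each, in treated muscle, and the design cannot separate them.

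Other splits of the libraries were counted for each fit. The real split of dexamethasone gave 4470 genes and the highest other split 0 (1 of 35 splits as large). That of LLC gave 128 against 22 (1 of 35). These shares argue against chance for both counts, though 1 of 35 is the smallest share that these splits can give. For old against young the real split gave 18 genes, the highest other 2 (1 of 10), and 17 lists, the highest other 17 (3 of 10); 10 splits are too few for a share under 0.05. For the siRNA the real split gave 0 genes and the highest other 10 (35 of 35). Chance is not excluded for the list calls of dexamethasone (18 against 21 in the highest other split, 8 of 35 as large), LLC (17 against 20, 8 of 35) or the siRNA (15 against 22, 20 of 35).

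The interaction test called 3416 genes between LLC and dexamethasone, with at least as many in 3 of 101 labellings (highest other 4977). It called 6 genes between LLC and old age, with at least as many in 3 of 101 (highest other 9). Both shares are under 0.05, which argues against chance without excluding it, since other labellings gave more genes. Labels were shuffled in all experiments at once, so the count cannot tell differing responses from a response in 1 experiment alone. The responses to dexamethasone and old age differed in 255 genes, as in 7 of 101 labellings (highest other 6735). Some of these labellings held the dexamethasone contrast itself, as given below, so the share does not exclude chance and cannot decide about it. Labellings that call several times the 255 genes point to a structure of the samples. Of these, 6735 and 3843 genes came with 0 of the 4 dexamethasone libraries under their real label and 1354 with 4, which is the treatment contrast itself, turned or as labelled. A further 5353 came with 1, and 2871 and 2243 with 3, which mix treated and control libraries, and the source of those counts stays open. For LLC and dexamethasone, 4977 genes came with 4 and 4708 with 3. Called in opposite directions under LLC and after dexamethasone, with a difference that passed, were Lyz1 (−2.18), Kdelr3 (−1.65), Col6a3 (−2.15), Fam20c (−1.27) and Egr1 (−1.94), of which only Lyz1 and Egr1 kept both calls after scaling. Ighm differed between LLC and old age (−2.70). Between dexamethasone and old age H2-Q7 (−3.09), Spint2 (−1.89), Ighm (−2.38), Ccl8 (−4.22) and H19 (1.74) differed. All of these genes were taken for opposite calls in the same libraries. A difference that passes was thus nearly given in advance and is no separate support.

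Within the groups of the dexamethasone, LLC and siRNA experiments, 272 tests of a gene or a library measure were made. In 16 of them, all of genes, 1 library lay far from the other 3, where chance gives about 1 in 20, or 13.6. Old and young muscle were not tested in this way. Fbxo32 was at 190 TPM in dexamethasone 2 (others 91.2 to 93.3), and Mstn at 15 TPM in dexamethasone 1 (20.3 to 21.4). Psmd2 was at 179 TPM in dexamethasone 2 (151 to 155). In the dexamethasone controls, Lcn2 was at 0.906 TPM in control 3 (0.547 to 0.598), Irf7 at 5.11 TPM in control 3 (11.7 to 12) and Clec3b at 46.1 TPM in control 2 (61.4 to 64.9). Arrdc2 was at 90.3 TPM in LLC 4 (51.6 to 54.5) and Fmo2 at 9.34 TPM in LLC 3 (13.2 to 14.2). In the LLC controls, Arrdc2 was at 29.3 TPM in control 1 (12.3 to 14.2), Fmo2 at 3.63 TPM in control 4 (4.37 to 4.47), Cited4 at 13.6 TPM in control 3 (17 to 17.7) and Myh1 at 4700 TPM in control 1 (2550 to 2680). Tnnt1 was at 12.4 TPM in Cyr61 siRNA 3 (5.99 to 6.34), where Parp6 was at 16.7 TPM (16.2 to 16.3). Fbxo32 was at 86.5 TPM in NT siRNA 4 (265 to 275) and Mstn at 5.8 TPM in NT siRNA 1 (13.6 to 15.4).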

How the results depend on the processing

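The alternatives with voom, with 2 changes at once and without the fourth siRNA libraries were chosen after seeing the data; the others were planned. Of 208 values of the 11 named genes called in old muscle, 113 kept direction and call and 95 kept direction but not the call; the numbers were 1465 and 171 of 1636 for the 75 genes of dexamethasone, and 516 and 146 of 662 for the 29 of LLC, with none reversed. The cause of the differences below was not tested, except that a stricter threshold calls fewer genes by construction. The estimation of array weights stopped before reaching its convergence tolerance for old age, for dexamethasone and for the interactions, with weights resting on few libraries, so those values are printed for completeness and not relied on. Depth limits genes of few reads most, and reads of genes with a searched length may be low by a whole factor.

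For old against young (18 genes called), the count was 0 with no filter, 0 with median-of-ratios scaling, 0 without mitochondrial and top 20 genes, 1 with quantile normalization, 5 with all 8 groups in the fit, 86 with robust variances, 56 with array weights, 152 with the replicate block, 2 with voom, 0 with voom and scaled sizes, 10 at a log2 change of at least 1 and 6 at an adjusted p under 0.01. Its 17 lists became 10 with all 8 groups, 11 with array weights and 0 with an estimated correlation. For dexamethasone (4470) the count was 1093 with scaling, 936 without mitochondrial and top 20 genes, 1229 with quantile normalization, 10306 with array weights, 1869 with voom, 1091 with voom and scaled sizes, 343 at a log2 change of at least 1, 1244 at an adjusted p under 0.01, 1599 with scaling and the replicate block and 203 with scaling and a log2 change of at least 1; with the replicate block alone it was 5735. Its 18 lists became 2 with an estimated correlation. For LLC (128) the count was 8 with no filter, 81 with a filter of 5 TPM, 351 with scaling, 357 without mitochondrial and top 20 genes, 374 with quantile normalization, 524 with array weights, 502 with the replicate block, 262 with voom, 406 with voom and scaled sizes, 38 at a log2 change of at least 1, 11 at an adjusted p under 0.01, 515 with scaling and less the third LLC library, and 320 with scaling and the replicate block. Its 17 lists became 0 with an estimated correlation. The siRNA calls by limma and voom stayed at 0 genes in all alternatives (82 to 892 at an unadjusted p under 0.05 with all libraries or without 1, except 50 without NT siRNA 1), and its 15 lists became 9 without mitochondrial and top 20 genes, 9 with quantile normalization and 0 with an estimated correlation.

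Responses that differed between LLC and old age (6) became 14 with a pseudocount of 0.1, 10 with 0.5, 14 with no filter, 2 with a filter of 5 TPM, 28 with scaling, 19 with quantile normalization, 10 with robust variances, 167 with array weights and 30 with the replicate block. Between dexamethasone and old age (255) they became 115 with a pseudocount of 0.1, 469 with no filter, 82 with a filter of 5 TPM, 443 with quantile normalization, 4832 with array weights and 408 with the replicate block. Between LLC and dexamethasone (3416) they became 812 with scaling, 1006 with quantile normalization and 8491 with array weights. Shared calls of LLC and dexamethasone (22) became 2 at an adjusted p under 0.01 and 52 with scaling. Those of dexamethasone and old age (4) became 1 at an adjusted p under 0.01, 1 with all 8 groups and 0 with scaling.

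Values or tests that changed direction were these. In old muscle, the tendon list (0.48) had a median of 0.20 with the test reversed under no filter, and the glycolysis list (0.04) had 0.0542 with quantile normalization and 0.0471 with array weights, again with the test reversed. Trim63 (0.09) was at −0.0663 with scaling, −0.0371 with array weights and −0.0774 with voom and scaled sizes, Mstn at −0.14 with array weights and −0.01107 with voom and scaled sizes, Myh2 at −0.51 and Myh4 at −0.0508 with array weights, and the ribosomal list at −0.0238 with voom and scaled sizes. After dexamethasone, the tendon list was at 1.23 with a filter of 5 TPM and the fast-fibre list at −0.0434 with quantile normalization. Myh2 was at −0.22 with scaling, −0.15 without mitochondrial and top 20 genes, −0.13 with quantile normalization, −0.0294 with voom, −0.22 with voom and scaled sizes and −0.22 with scaling and the replicate block. Myh1 was at −0.22, −0.15, −0.0332 (voom), −0.23 (voom, scaled sizes) and −0.22 (scaling and block), and Myh4 at −0.14 with scaling, −0.15 with voom and scaled sizes and −0.14 with scaling and block. Under LLC, Myh1 was at 0.15 with quantile normalization and 0.0746 with array weights. With the siRNA, array weights gave 0.0562 for the mitochondrial list, 0.0163 for fatty acid oxidation, 0.20 for red blood cells, −0.014 for Fbxo32, −0.00632 for Mstn and −0.008179 for Myh4.

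Leaving out each library in turn gave 0 to 274 genes for old age, 1918 to 8715 for dexamethasone, 19 to 361 for LLC, and 9 to 18 lists for the siRNA. The ranges below are followed by the libraries whose absence changed the direction. In old muscle the range was −0.12 to 0.0637 for the mitochondrial list (old 3), 0.04 to 0.21 for the ribosomal list (young 1, by its test), −0.008238 to 0.0878 for fatty acid oxidation (young 3), −0.063 to 0.19 for Trim63 (old 3 and young 3), −0.15 to 0.83 for Myh2 (old 3 and young 1), −0.007684 to 0.26 for Mstn (young 3) and −0.0463 to 0.40 for Myh4 (young 3). After dexamethasone it was −0.15 to 0.40 for Myh2 (control 1 and dexamethasone 2) and −0.0389 to 0.38 for Myh4 (dexamethasone 2). Under LLC it was −0.40 to 0.10 for Myh1 (control 1 and LLC 4) and −0.007256 to 0.61 for Myh2 (control 2). With the siRNA it was −0.40 to 0.42 for collagens (Cyr61 siRNA 1), 0.011 to 0.30 for the unfolded protein response (Cyr61 siRNA 3, by its test), −0.20 to 0.11 for fatty acid oxidation (NT siRNA 1) and 0.0589 to 0.19 for endothelial genes (NT siRNA 2, by its test). It was −0.15 to 0.52 for Myh2 (Cyr61 siRNA 3, NT siRNA 3 and NT siRNA 4), −0.21 to 0.46 for Fbxo32 (NT siRNA 4) and −0.12 to 0.54 for Trim63 (NT siRNA 4). Whether replicate numbers pair the samples stays unsettled: correlations of the residuals of equal numbers ran from 0.044 to 0.135 (old), 0.027 to 0.498 (dexamethasone), 0.041 to 0.374 (LLC) and 0.094 to 0.498 (siRNA), not all over 0.1, and not every sample correlated best with its own number, so the replicate block stays an alternative.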

Other observations

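The genes below were chosen after their values were seen, and the lists were planned. With an estimated correlation camera called 2 lists after dexamethasone as fitted, and none of the lists below was among them. After dexamethasone 9 of 13 slow-fibre contractile genes rose, 9 upward and 1 downward adjusted over the list alone and 6 upward and 1 downward after scaling, with a median 0.72 above the median gene, although camera did not call the list as fitted (adjusted p = 0.118; 0.00151 after scaling). Tnnc1, the slow troponin C, was at 71.3 ± 25.1 TPM (n = 4) against 15.9 ± 7.17 TPM (n = 4), a relative log2 change of 1.79, and Tnni1, the slow troponin I, changed by a relative 1.78 and Tnnt1 by 1.48. Of 18 YAP/TAZ targets 10 rose, 12 adjusted over the list alone and 5 after scaling, with a median of 0.17 (camera adjusted p = 0.102; 0.00473 after scaling). Ankrd1, a repeat protein of stressed muscle, was at 174 ± 53.7 against 59.6 ± 19.3 TPM and Ctgf at 20.2 ± 5.50 against 9.05 ± 3.30 TPM, beside Cyr61, which belongs to the same list. Of 21 cell cycle genes 12 rose, 14 adjusted over the list alone and 3 after scaling (camera adjusted p = 0.18; 0.00296 after scaling), with Rrm2, a subunit of ribonucleotide reductase, at 7.12 ± 1.70 against 2.64 ± 0.553 TPM. Of 6 neutrophil genes 4 rose and 1 fell, Retnlg, as after scaling, and the list was not called (adjusted p = 0.355; 0.0123 after scaling). Under LLC the clock repressors Per1 (22.8 ± 6.95 against 9.73 ± 4.58 TPM) and Per2 (5.75 ± 1.69 against 2.56 ± 1.01 TPM) missed the threshold (adjusted p = 0.0733 and 0.0516; 0.0340 and 0.0261 after scaling), and the clock activator Arntl was at 5.30 ± 1.90 against 9.16 ± 1.44 TPM (adjusted p = 0.111).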
